A study of Mus musculus with 2 samples.

How the data were processed

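Immunoprecipitated DNA of mouse ES cells was sequenced in 2 libraries, 1 labelled H2ABbd ChIP-seq and 1 labelled MeDIP. No control (input) library was used here. Per the labels' protocols, chromatin for the ChIP was crosslinked with formaldehyde and sonicated, and DNA for the MeDIP was sonicated, ligated to adaptors, denatured and precipitated with an antibody against methylated cytosine. Both libraries were amplified by PCR, with more cycles for the ChIP. Per the submitters' processing notes the reads were checked with FastQC and aligned to mm9 with Bowtie; their versions, the mismatches allowed and the treatment of reads with several possible positions are not given in the sources used here. The deposited files hold 1 line per aligned read of 42 bp with its position, strand and read name. The deposited score column holds 255 on every line and was not used. Reads were neither deduplicated nor grouped into peaks before deposit, as the files show. How reads of repeated sequence were placed decides the level at repeats, and no input library corrects for copy number.

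The name of each deposited file gives the antibody of the other sample. Groups were taken from the sample labels. A check of the labels against CpG density, CpG islands and promoters had been set, but it needs the mm9 sequence and annotation, which were not used here, so the labels stand unchecked. For the same reason no gene names, promoters, exons or CpG islands are given and regions are named by mm9 coordinates alone (1-based), and the gene lists set for this study were not analysed here. The gene tables at hand were on another build and gave no coordinates.

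From the lines, distinct positions (chromosome, 5' end and strand) were counted once, each read start was moved 100 bp towards its 3' end, and reads were counted in 1 kb bins on chromosomes 1 to 19 and X. Lines with broken field separators, 8 in the file of the library labelled H2ABbd and 1 in the other, were left out. RPM values were computed from the distinct reads of each library. A bin was called enriched at an adjusted Poisson tail of 0.01 (Benjamini-Hochberg over bins) and at least 4 times the mean over non-empty bins of its chromosome. Non-empty bins are those with a read in either library. The tail served as a filter on the bins of 1 library and not as a test of conditions. Adjoining bins were merged. Correlations used log2(RPM + 0.1). Intervals are exact Clopper-Pearson for shares and, scaled, for chromosome densities, and exact Poisson for counts. Those of the ratio in a single 1 Mb window come from its read counts. For other ratios, correlations and levels they come from 1000 bootstrap draws over 1 Mb blocks. All are at 95%. PCR reads without molecular identifiers are not independent molecules, so intervals and floors from counts cover counting error only.

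Named regions are, per library, the 5 densest enriched regions of 2 kb or longer, the 5 regions enriched in both with the highest lower fold, and the 3 regions with the highest ratio in each direction among those with at least 50 distinct reads in the higher library. Regions at 10 times the fold threshold or more in both libraries are called possible repeat pile-ups. The tests of the main comparisons, this rule and 57 alternatives were fixed before the data were examined, while the closing section names the tests and settings chosen later. Of the 57, 51 were run and 6 that need annotation or peak files were not. The alternatives kept all reads, thinned the deeper library to 1397289 distinct reads, and changed bin size, shift, thresholds, pseudocount and the bins used. Calls at a given true fold were worked out from the Poisson distribution and the lowest count called on each chromosome. The calling step was tested on simulated data of 2299806 bins at the depth of each library. It called 0 unraised bins at the depth of the library labelled H2ABbd and 1 at that of the library labelled 5mC. In the real data the variance of counts over bins was 29.2 (H2ABbd) and 10.2 (5mC) times the mean. Without the most covered bins it was 2.58 and 1.83 times the mean. The Poisson tail assumes a variance equal to the mean, so the simulation does not give the number of false calls in the real data. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.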

Results

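The series asked where the histone variant H2ABbd lies in the genome of mouse embryonic stem (ES) cells and whether the same regions carry methylated DNA. H2ABbd is a short H2A variant of mammals. ES cells are pluripotent cells derived from the early embryo, and here they were grown with the cytokine LIF and without feeder cells. In 1 library chromatin was immunoprecipitated with a rabbit antibody against mouse H2ABbd (ChIP-seq), and in the other denatured genomic DNA was immunoprecipitated with a monoclonal antibody against 5-methylcytosine (MeDIP-seq). There was 1 library per group, so no difference between the libraries has a replicate check, no test across conditions was made, and all intervals cover counting error only or, where stated, the spread over 1 Mb blocks of the genome. The names of the deposited files give the antibodies the other way round from the sample labels. Groups follow the labels, so the text writes "the library labelled H2ABbd" and "the library labelled 5mC", and every direction below rests on those labels.

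The library labelled H2ABbd held 3503839 aligned reads at 1397289 distinct positions, so 60.1% of its reads repeated a position and strand already seen (exact Clopper-Pearson 95% interval 60.1 to 60.2%). Of its distinct positions 80.0% held 1 read, so the repeats lay on a minority of positions, many of them in the few short regions described below. The library labelled 5mC held 9266471 reads at 8056333 distinct positions, with 13.1% repeats (13.0 to 13.1%). It was thus 2.64 times deeper in reads and 5.77 times deeper in distinct positions. Read starts on opposite strands lay most often 110 to 119 bp apart in the library labelled H2ABbd, at 3.70 times the background of longer distances, and 70 to 79 bp apart in the library labelled 5mC, at 1.95 times.

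**Figure D1:**
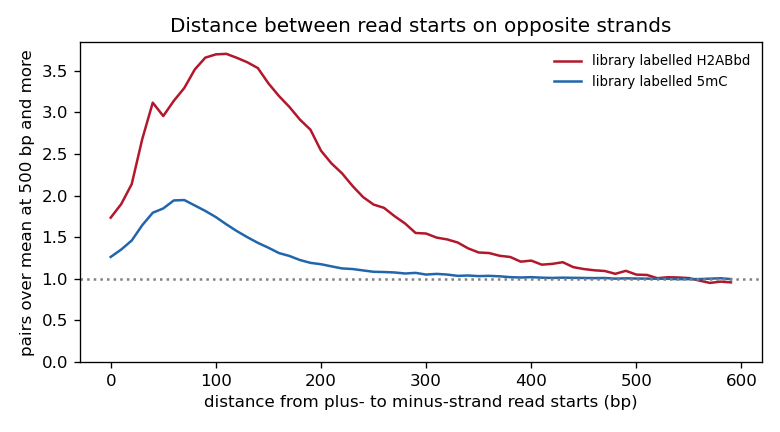
Number of pairs of distinct read starts on opposite strands against their distance in bp, divided by the mean at distances of 500 bp and more, for the 2 libraries (1 line each). The line of the library labelled H2ABbd peaks at 3.70 and that of the library labelled 5mC at 1.95, at a shorter distance.

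A few short regions held a large part of the reads of the library labelled H2ABbd. A stretch of chromosome 2 (mm9, 98502001 to 98508000) held 28.0% of all its reads, and a 40 kb stretch of chromosome 9 (2999001 to 3039000) held 16.6%. In the library labelled 5mC the same regions held 4.25% and 3.42%. Chromosome 9 from 35112001 to 35114000 held 3.10% against 0.396%, and chromosome 12 from 3109001 to 3111000 held 2.91% against 0.438%. In all, 105 bins of 1 kb in 51 regions lay at least 40 times above the chromosome mean in both libraries. By the rule for naming regions these are possible repeat pile-ups, and they held 51.7% of all reads of the library labelled H2ABbd and 9.39% of those of the library labelled 5mC. Counted once per position they held 3.37% and 0.830%. The chromosome 2 region had 3431 distinct positions in the library labelled H2ABbd and 3942 in the deeper one, so at such regions the number of distinct positions follows depth poorly and the fold understates the reads.

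In the library labelled H2ABbd 27187 bins of 1 kb were enriched over the mean of their chromosome, 1.18% of the bins tested, and they formed 23165 regions. Most regions, 20198, were a single bin, and the median enriched bin lay 12.5 times above the mean. The densest regions of 2 kb or longer were those on chromosomes 2 (98502001 to 98508000, 929-fold, Poisson 95% interval 898 to 961) and 9 (2999001 to 3039000, 926-fold, 916 to 936), followed by chromosome 18 from 90771001 to 90773000 (784-fold, 731 to 840), chromosome 2 from 181747001 to 181749000 (641-fold, 597 to 687) and chromosome 9 from 35112001 to 35114000 (317-fold, 292 to 344). Chromosome 12 had the most enriched bins, 19.9 per 1000, and chromosome 3 the fewest, 7.93 per 1000. Bins were held against the mean of their own chromosome, so these rates also depend on those means. With a mean of 0.622 distinct reads per autosomal bin, a bin was called from 5 to 7 reads depending on the chromosome. With Poisson counts, 3.91% of bins truly raised 4-fold, 35.2% of those raised 8-fold and 89.1% of those raised 16-fold would reach these counts. In simulated libraries with few raised bins, where the adjusted threshold is stricter, 12% of bins raised 8-fold and 62% of those raised 16-fold were called. The number of enriched bins was 16288 with the deeper library thinned, 17114 in 5 kb bins, 14537 with the local mean as well and 8816 at an adjusted 1e-05. Thinning left the reads of the library labelled H2ABbd unchanged. It lowered the number of bins with a read in either library, over which the mean is taken. Without the 0.1% most covered bins that number was 1365969 thinned against 2296104. Enrichment in this library thus depends on the depth of the other.

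In the library labelled 5mC 11677 bins were enriched, 0.508% of the bins tested, in 9671 regions, with a median of 4.89 times the chromosome mean. Besides the chromosome 9 and chromosome 2 regions (246-fold and 184-fold), its densest regions were chromosome 17 from 39979001 to 39986000 (237-fold, 232 to 243), chromosome 17 from 13743001 to 13747000 (171-fold, 165 to 178) and chromosome 10 from 7229001 to 7238000 (131-fold, 127 to 135). The last lay 23.7-fold above the mean in the library labelled H2ABbd. Chromosome 1 had the most enriched bins, 7.68 per 1000, and chromosome 9 the fewest, 2.70 per 1000. Bins were held against the mean of their own chromosome, so part of this ranking can come from those means. The density of distinct reads was 0.837 of the autosomal mean on chromosome 1 and 1.18 on chromosome 9, which holds the 40 kb stretch. Calls needed 12 to 17 reads, which 47.3% of bins truly raised 4-fold and 99.7% of those raised 8-fold would reach with Poisson counts. In the simulated libraries 30% and 100% of such bins were called. The number of enriched bins depended on the setting: it was 735 with this library thinned to the distinct positions of the other, 0 when the 0.1% most covered bins were left out as well, 902 in 5 kb bins, 1927 with the local mean as well, 1772 at 8-fold or more and 4718 at an adjusted 1e-05. The 0 was largely set by the choice, since it left out the bins with the most reads.

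Regions enriched in the library labelled H2ABbd and in the library labelled 5mC overlapped. Of the enriched bins 2811 were called in both libraries, where independent placement gives 138, a ratio of 20.4 (18.9 to 22.1 over 1 Mb blocks). In 100 shifts of one set along its chromosome 109 to 207 bins coincided. The shared bins were 10.3% of those of the library labelled H2ABbd and 24.1% of those of the library labelled 5mC, so most enriched bins of either library were not called in the other. Without the 0.1% most covered bins of either library 1715 bins were shared against 111, a ratio of 15.4 (14.3 to 16.6). The ratio was 9.92 with calls within 1 bin counted as shared, 31.4 in 500 bp bins, 43.6 at 8-fold or more, 51.0 with the deeper library thinned and 62.4 at an adjusted 1e-05. Thinned and without the most covered bins, no bin of the library labelled 5mC was called and none was shared. That outcome was largely set by the choice, since bins are called for having many reads and those with the most were left out. It therefore says nothing about the overlap.

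Among the regions enriched in both, the highest lower-of-the-2 folds were those of the chromosome 9 stretch (926-fold and 246-fold), chromosome 17 from 39979001 to 39986000 (267-fold and 237-fold), X from 166527001 to 166528000 (1400-fold and 202-fold), chromosome 2 from 98502001 to 98508000 (929-fold and 184-fold) and chromosome 18 from 90771001 to 90773000 (784-fold and 126-fold). All 5 meet the rule for possible repeat pile-ups. Other regions were enriched in 1 library alone. Chromosome 3 from 137331001 to 137333000 had 51 distinct reads in the library labelled H2ABbd (53.5-fold, 39.8 to 70.4) and 5 in the library labelled 5mC (0.815-fold, 0.265 to 1.90). Chromosome 1 from 95670001 to 95671000 had 50 and 5, and chromosome 3 from 140434001 to 140437000 had 72 and 8. In the other direction chromosome 7 from 71615001 to 71622000 had 148 distinct reads in the library labelled 5mC and 0 in the library labelled H2ABbd, at least 8.55-fold higher per distinct read against a floor of 3 counts over the region. Chromosome 12 from 4219001 to 4222000 had 127 and 0 (at least 7.34-fold higher), and chromosome 9 from 100999001 to 101001000 had 107 and 0 (at least 6.18-fold higher).

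At bins enriched in the library labelled H2ABbd the mean level of the library labelled 5mC was 3.23 times its genome mean (2.66 to 4.20 over 1 Mb blocks). At bins enriched in the library labelled 5mC the mean level of the library labelled H2ABbd was 14.6 times its mean (9.08 to 24.8). A small number of very deep bins carried part of both values, which were 2.06 (2.04 to 2.08) and 5.25 (5.03 to 5.47) without the 0.1% most covered bins. The 5mC level was 9.16 with all reads kept, 5.53 at an adjusted 1e-05 and 1.32 thinned without the most covered bins, and the H2ABbd level was 109.7 with all reads kept, 80.0 with the deeper library thinned, 64.3 at bins of 8-fold or more, 28.8 at an adjusted 1e-05 and 28.5 in 5 kb bins. The raised level was local. Around regions of the library labelled H2ABbd the library labelled 5mC stood at 2.03-fold in the densest bin and 1.28-fold at 5 kb upstream. Around regions of the library labelled 5mC the library labelled H2ABbd stood at 5.32-fold and 1.75-fold. Of the bins enriched in the library labelled 5mC 19.2% held no read of the library labelled H2ABbd, against 68.2% of all bins.

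**Figure D2:**
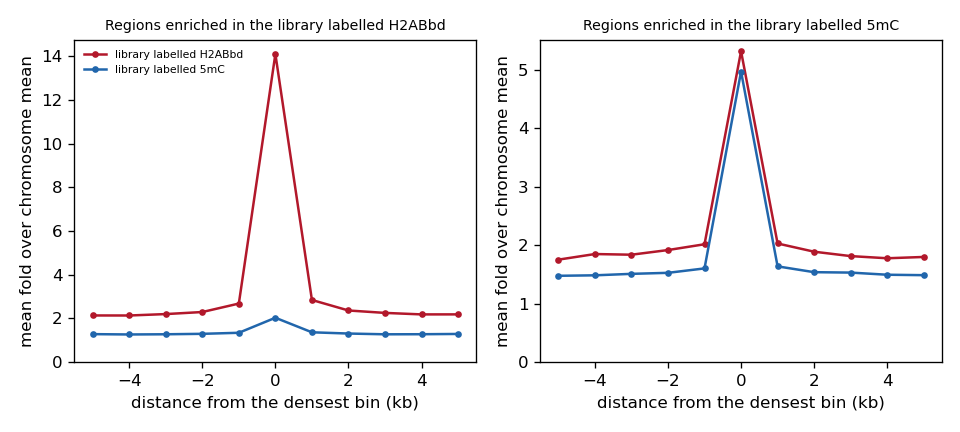
Mean fold over the chromosome mean (vertical axis) in 1 kb bins up to 5 kb either side of the densest bin of each enriched region, for 23052 regions of the library labelled H2ABbd (left) and 9029 regions of the library labelled 5mC (right), without the 0.1% most covered bins. Each line is 1 library, and the library not used to choose the regions rises to 2.03 on the left and 5.32 on the right at the densest bin.

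Over all 2164448 autosomal 1 kb bins with a read in either library, the levels of the libraries were weakly correlated across bins (Pearson r = 0.207, 0.200 to 0.214 over 1 Mb blocks, Spearman rho = 0.215). Bins are not independent replicates. Shifting one library along the chromosomes gave -0.0062 to 0.0193 in 20 shifts. Random splits of the reads of 1 library correlated in 1 kb bins at r = 0.298 for the library labelled H2ABbd and 0.110 for the library labelled 5mC. These bins were kept for a read in either library, and only 1.89% of such bins, X included, held none of the library labelled 5mC. That choice can lower the value of its splits, so 0.110 alone does not measure its reproducibility. In larger bins the splits of the library labelled 5mC had the higher value: 0.411 (H2ABbd) and 0.558 (5mC) in 5 kb bins, and 0.871 and 0.959 in 100 kb bins. In 500 bp bins r was 0.0276 (0.0203 to 0.0346), in 5 kb bins 0.465 and in 100 kb bins 0.803, and with a pseudocount of 0.01 RPM it was 0.109. With the library labelled 5mC thinned to the same number of distinct positions the sign in 1 kb bins turned to -0.442 over bins with a read in either library and was 0.166 over all bins.

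Among chromosomes 1 to 19 and X the libraries differed on X and on chromosome 12, and near chromosome ends. The density of distinct reads on X was 0.546 of the autosomal mean in the library labelled H2ABbd (0.541 to 0.550) and 0.694 in the library labelled 5mC (0.692 to 0.696), and with all reads kept it was 0.257 and 0.633. Relative to the library labelled 5mC, the library labelled H2ABbd was denser on chromosome 12 (1.22 times, and 1.22 without the 0.1% most covered bins) and sparser on chromosome 14 (0.866 and 0.885). On chromosome 9 the ratio was 1.29 with all bins and 0.966 without the most covered bins, which include the 40 kb pile-up there. In windows of 1 Mb the ratio of the libraries had a median of 0.893 over 2399 autosomal windows (5 to 95% range 0.656 to 1.45) and of 0.757 over 163 windows of X. In the last 10 Mb of the autosomes the median was 1.07 against 0.885 elsewhere, and it was higher there on 15 of 19 autosomes. The 5 highest of all windows adjoined on chromosome 12 between 109000001 and 114000000, at 2.31 to 3.13. The window with the lowest ratio was X from 80000001 to 81000000, at 0.356 (0.286 to 0.437).

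**Figure D3:**
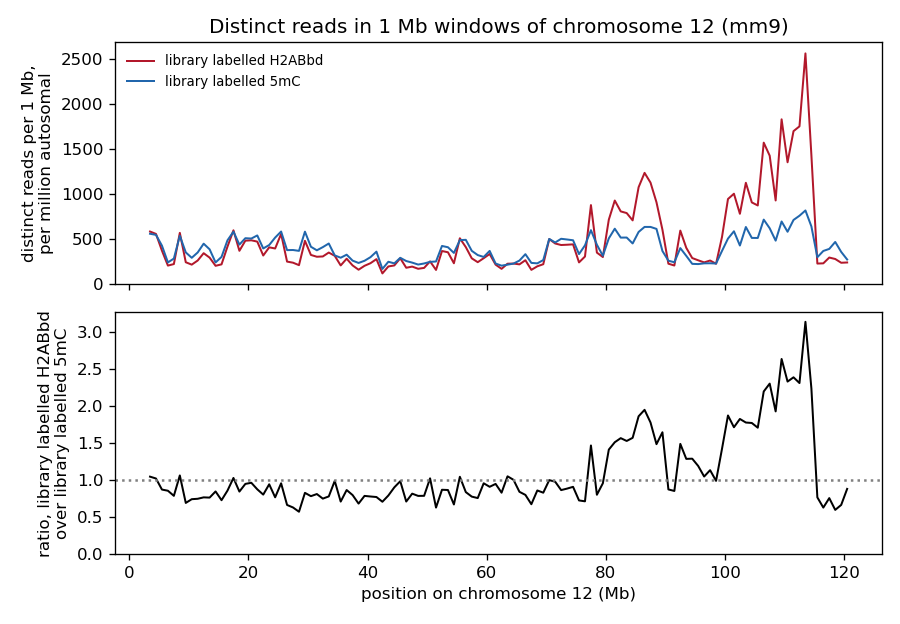
Distinct reads per 1 Mb window of chromosome 12 scaled to the autosomal distinct reads of the library (upper panel, 1 line per library) and their ratio (lower panel), against position in Mb, without the 0.1% most covered bins. The ratio reaches 3.13 in the window from 113000001 and is 0.765 in the window from 115000001.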

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

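The tests of file order and read names at the chromosome 7 locus, and those of copy number on reads not used for calling, were chosen only after the results were seen.

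The file of the library labelled H2ABbd ends with 8 lines whose field separators are broken, and the report's comparisons leave them out. All 8, and the 1 such line of the other file, lie at 1 locus of chromosome 7 (mm9, within 150481001 to 150482000), 6 of the 8 share a start and 6 share a y coordinate of 99999 in the read name. Counted from 0, all 9 start at a multiple of 10, as 10.3% and 10.0% of the regular lines of the libraries do, though they hold only 3 different starts. Reads of regular lines at this locus also lay close together in the file of the library labelled 5mC, with 8 neighbouring pairs within 0.02% of the lines where 0.140 were expected, the lowest Poisson tail (3.23e-12) of 640931 bins with 5 to 300 reads. The next lowest tail was 8.63e-08. In the library labelled H2ABbd the regular lines of the locus had 3 such pairs against 0.185, a tail of 0.000922, which ranked 5 among 68723 bins. The bin is called enriched from its regular lines in both libraries (40.6-fold, 26.5 to 59.5, and 6.51-fold, 4.17 to 9.68).

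For the reads that lie close together in the file at this locus, several accounts were weighed. Neighbouring clusters of 1 amplified fragment are argued against by a median distance of 6525 units on the tile between such reads, and none of the 11 pairs of both libraries shared a position. Sequenced fragments of an enriched region stay open, since the 8 close pairs are the pattern itself. The rule also asked that no other bin have a tail below 1 over the number of bins, and the next lowest was 8.63e-08. Another bin held 24 pairs, but this raw count grows with the reads of a bin and cannot be compared with the 8. Lines entered or changed after alignment stay open too: of 12770319 reads 2 pairs of names lay within 10 tile units and both hold a read of this locus, but only 1 pair has regular lines on both sides, and the smallest distance elsewhere was 11.2. How such lines arose was not tested. With the lines with broken separators kept, the correlation, enriched bins, overlap and levels stayed within their intervals or counts.

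Bins enriched in both libraries exceeded independent placement by 20.4 times. The most covered 0.1% of bins do not account for the excess, since 15.4 times remained without them. Copy number or collapsed repeats that raise both libraries alike stay open. Outside the most covered bins, 195 bins were called on part of the reads of each library. On the remaining reads their H2ABbd fold over the 5mC fold was 2.66 (2.38 to 2.98). With the most covered bins kept the folds over 917 bins were 93.7 and 31.3 (interval of the ratio 2.37 to 3.38). Among them were deep bins where distinct positions follow depth poorly. The folds of these bins were not equal, but calls in the sparser library need a higher fold. Outside the most covered bins, bins called on part of 1 library had own folds of 13.0 (H2ABbd) and 5.02 (5mC) on its remaining reads. The choice of bins thus favours a ratio above 1, which cannot decide. The ratio was 1.67 (1.30 to 2.11) at all bins enriched in the library labelled 5mC, shared or not. It was 0.985 (0.909 to 1.07) at those called on part of its reads outside the most covered bins. The interval of the latter includes 1, the outcome set for libraries raised alike, and that of the former does not. Equal means over bins do not show that single bins are raised alike. At bins called on part of the reads of the library labelled H2ABbd, likewise without the most covered bins, the inverse ratio was 0.155 (0.151 to 0.160). This is the 5mC fold over the H2ABbd fold. Reads of repeated sequence placed at 1 of several positions may contribute: the strand split of shared bins had a mean chi-square of 11.3 (9.43 to 13.5) in the library labelled H2ABbd against 2.04 at bins enriched in it alone, and 3.42 in the library labelled 5mC, but without the most covered bins these were 3.32, 1.87 and 1.71. No input library or mm9 sequence was used here, so H2ABbd and DNA methylation on the same regions, as a biological account, was not tested.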

How the results depend on the processing

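Keeping the lines with broken separators, bins of 100 kb, both settings that pair thinning with another choice, and X without the most covered bins were chosen after seeing the data. Values are given in the order correlation, enriched bins of the library labelled H2ABbd and of the library labelled 5mC, observed over expected overlap, 5mC level at H2ABbd bins and H2ABbd level at 5mC bins, where they moved. With all reads kept they were 0.230 for the correlation, 18.3 for the overlap, and 9.16 and 109.7 for the levels, and the X density was 0.257 and 0.633. With the deeper library thinned they were -0.442, 16288, 735, 51.0, 2.39 and 80.0. The reversed correlation needed both thinning and the choice of bins with a read in either library. Over all bins the thinned libraries gave 0.166, and without thinning that choice gave 0.207. Thinned and without the top 0.1% bins they were -0.454, 15481 and 0, with a 5mC level of 1.32, and no overlap or H2ABbd level could be computed. The 0 was largely set by leaving out the bins with the most reads. In 500 bp bins the correlation was 0.0276 and the overlap 31.4. In 5 kb bins the values were 0.465, 17114, 902, 17.1, 2.19 and 28.5, and in 100 kb bins the correlation was 0.803. Without the top 0.1% bins they were 0.195 for the correlation, 15.4 for the overlap and 2.06 and 5.25 for the levels, and X density of the library labelled H2ABbd was 0.538. With a fold of 2 or more the overlap was 17.9. With a fold of 8 or more there were 1772 bins of the library labelled 5mC, an overlap of 43.6 and an H2ABbd level of 64.3. At an adjusted 1e-05 the values were 8816, 4718, 62.4, 5.53 and 28.8. The correlation was 0.109 and 0.298 with pseudocounts of 0.01 and 1 RPM, 0.298 over bins with a read in both, and 0.291 over all bins. Counting calls within 1 bin gave an overlap of 9.92, and the 1% of bins with most reads gave 13.8. With the local mean as well there were 14537 and 1927 enriched bins.

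The overlap lay above 9 times expectation in every setting that gave one, and both levels stayed above 1 in every setting that gave a value. The alternatives set beforehand gave 61 values and those chosen after seeing the data 14. Of these 75 values 27 stayed inside the interval of the main value or within 1.5 times its count, 46 moved and 2 reversed. Apart from the thinned correlation the causes were not tested. The lower thinned count of the library labelled H2ABbd follows from the bins over which its mean is taken, since its reads were unchanged. Autosomal 1 kb bins held on average 0.622 distinct reads of the library labelled H2ABbd and 3.55 of the library labelled 5mC, which limits calls of weak enrichment in both. Alternatives for promoters, gene lists and peak files were not run, because no mm9 annotation was used here and the files hold reads. No paired analysis was possible because each group has 1 library.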

Other observations

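The tests of the chromosome 12 segment were chosen only after the result was seen, from a scan of all 2562 windows.

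On chromosome 12 the libraries parted over a long stretch. In a scan of 19 autosomes for the segment of 5 to 40 Mb whose ratio of the libraries is raised most, by likelihood, over the rest of its chromosome, the best segment lay at 80000001 to 114500000. Inside it the library labelled H2ABbd was 2.82 times denser than on the rest of the chromosome and the library labelled 5mC 1.28 times, a ratio of 2.20. The best segments of the other 18 autosomes, chosen in the same way, had ratios of 1.17 to 1.81, among them chromosome 8 from 121500001 to 127500000 (1.81) and chromosome 4 from 128000001 to 156000000 (1.51).

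A gain of the segment to the same degree in the cells of both libraries would leave the ratio as elsewhere. The median ratio in its 1 Mb windows was 1.67, above the 95% point of 1.36 of 2096 windows elsewhere. Since the segment was picked for its ratio, this restates the pattern and is no test of such a gain. The windows elsewhere had reads of the library labelled 5mC within the wide range of the segment (1675 to 6152) and were not matched more closely. A few enriched regions inside the segment are argued against as its whole source, since without the bins enriched in either library the ratio to the rest of the chromosome was 1.89 (1.75 to 2.02 over 1 Mb blocks), above the 1.13 to 1.59 of the other 18 autosomes, although bins raised too little to be called remain in it. A larger copy number gain in the cells of the library labelled H2ABbd, or raised signal over the stretch, stays open. The log likelihood ratio of 4599 was over that of any other autosome (next 1474, chromosome 4). It is the measure that picked the segment, so it bears on neither account. A median of 49.4% of 1 kb bins had no read of the library labelled H2ABbd against 72.1% in the windows elsewhere. This does not stand apart from single windows (5% point 46.8%). The accounts cannot be told apart without an input library, and single windows inside went down to a ratio of 0.851.

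In the most covered 0.1% of bins 38.6% of the distinct reads of the library labelled H2ABbd lay on the plus strand, against 55.5% in its other bins. In the library labelled 5mC the shares were 51.9% and 52.8%.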
